A study of Danio rerio with 9 samples.

How the data were processed

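The study used a custom 2-colour Agilent oligonucleotide array, with 1 array for each of 9 transgenic RNA pools from zebrafish. Per the labels, RNA was isolated from snap-frozen pools of 10 caudal fins or 6 fin tumours, amplified as aminoallyl RNA and coupled to a dye, Cy3 for wild-type fin and Cy5 for the transgenic tissue, on every array. The extraction text of the labels speaks of homogenized embryos, while the sample fields give fins and fin tumours, which the files do not resolve. No array had the dyes exchanged, so a probe's dye bias stays in each ratio to wild-type and cancels between transgenic groups. The labels name separate pools within each group; they do not tie wild-type pools to arrays. The submitters' processing notes name Agilent Feature Extraction 9.5.3.1, and the file headers give the protocol GE2-v5_95_Feb07 and the array design 015747.

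Per the file headers, the deposited scanner files hold the mean and the local background median intensity of each spot in each channel, not yet normalized, together with flags. They also hold the scanner software's log10 ratio of Cy5 over Cy3, after its own background subtraction and dye normalization. The authors' deposited value table holds the same log10 ratios: for each array the largest difference from the scanner's ratio was 0 and the median ratio was 0. It was therefore no separate alternative. Each array has 44787 spots, of which 1417 are controls. The 43370 other spots carry 42152 distinct sequences, 624 of them on several spots and 1 on 172 spots.

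The intensities were background corrected with normexp (offset 50) and normalized within each array by loess, with control spots and flagged spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots flagged as non-uniform or population outliers were left out, saturated spots were kept, and spots of identical sequence were averaged. Signals of a single channel were rebuilt from the ratio and the mean log2 intensity of the channels. That mean was first quantile normalized between arrays. The Cy5 signals alone and the normalized Cy3 signals are therefore not fully free of the other channel. A probe was tested if Cy5 was well above background on all 3 arrays of at least 1 group, or Cy3 on at least 3 of the 9 arrays; 32039 probes passed and 10113 did not. The median Cy3 intensity per array ranged from 364 to 566 and the median Cy5 intensity from 849 to 1011, and at most 26 spots of an array were saturated in Cy5. A model with 3 group means was fitted to all 9 arrays (residual df 6, prior df 3.76), with eBayes and Benjamini-Hochberg adjustment over the 32039 probes, and an adjusted p under 0.05 was called. Each group mean was tested against 0, which compares the transgenic with the wild-type channel, and the groups against each other. Tested on simulated data of 32039 probes, this procedure recovered 91% of the log2 changes of 2 and 70% of those of 1 for V600EBRAF against wild-type, and 87.8% and 39.5% for RGP against V600EBRAF. For changes of 1 it recovered 55% for RGP and 56% for VGP against wild-type, and for VGP against RGP 84.8% of changes of 2 and 30.7% of changes of 1. In the simulation 100 probes per group changed by each size, with independent noise and no slide effect. Far more probes were called in the data, so these shares do not give the recovery of the reported tests.

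The gene lists and marker panel fixed before the data were examined could not be used, because the files pair the probes with no gene names and the reference tables used here hold no probe sequences. For the same reason no list of tissue markers could show the cell make-up of the samples. The rule for named genes, fixed before the data were examined, took per comparison the rising and falling named genes with the largest log2 change among those called, well above background in at least 1 channel of all arrays compared and moving the same way on all of them. Without gene names it was applied to probes, and the list was shortened afterwards to the first 2 rising and the first 2 falling probes. In place of the gene lists, probes were grouped by peptide motifs in the sense reading frames of their sequences. The motifs were fixed after the files had been opened but before any ratio was looked at. Classes of at least 5 tested probes with few hits on the reverse strand were tested with camera (preset correlation 0.01, and an estimated correlation); these were the collagen repeat (6 probes), the homeodomain (6), the immunoglobulin fold cysteine (6) and the endoplasmic reticulum retention signal (5). Without a block no class passed an adjusted p of 0.05 in any of the 6 comparisons; the lowest was 0.07, for the retention signal between RGP and V600EBRAF, with an adjusted p of 0.22 with an estimated correlation. With the replicate block it was 0.039, and 0.23 with that block and an estimated correlation. Members of other classes are given singly and were picked for the text after their values were seen. A motif describes a peptide and names no gene. The true reading frame of a probe was not known. A probe said to encode a motif holds a match in any forward frame, which can also arise by chance. On the reverse strand the collagen repeat and the retention signal each matched 1 probe, and the homeodomain and immunoglobulin fold motifs matched 0.

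The arrays lay on 3 slides. Slide 1 held replicates 1 and 2 of V600EBRAF and of RGP, slide 2 held replicate 3 of all 3 groups, and slide 3 held replicates 1 and 2 of VGP. Slides 1 and 3 were scanned on one day and slide 2 on another. Replicate numbers come from the sample titles. Deviations from the group means correlated between arrays of the same number by 0.33, 0.19 and 0.60 for V600EBRAF and RGP (replicates 1, 2 and 3), by 0.16, 0.24 and 0.43 for RGP and VGP, and by 0.18, -0.02 and 0.39 for V600EBRAF and VGP. By the rule that every pair lies over 0.1, the first 2 of these combinations passed, and the replicate block is given where it moves a count by over 1.5 times. The rule cannot show that replicates 1 and 2 are paired. Deviations within a group sum to 0, so a shared deviation of the replicate 3 arrays alone raises all 3 correlations. The difference of replicates 1 and 2 correlated by 0.07 between V600EBRAF and RGP and by 0 between RGP and VGP. Slide, scan day and replicate number were each fitted as blocks. The other alternatives were no background correction, a normexp offset of 16, median centring, scaling between arrays, the scanner's ratio, other probe filters, variance priors with trend or robust, only the arrays compared, the Cy5 channel alone, flagged spots kept, a 2-fold minimum and leaving out each array. Scan day, the first scan day alone, 1 probe per cluster of probes sharing 20 bases, and all alternatives for peptide classes and for the other bright probes were added after the data were seen.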

Results

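RNA abundance was measured in zebrafish caudal fins and in tumours growing within caudal fins. The transgenic fish carried an activated oncogene in the melanocyte lineage, either V600EBRAF, a mutant form of the kinase BRAF, or V12RAS, a mutant form of the GTPase HRAS. The V12RAS fish gave 2 kinds of sample, named RGP and VGP in the labels, which give the abbreviations only; the VGP samples are labelled as melanoma. Each of the 9 arrays compared one transgenic RNA pool, labelled with Cy5, with wild-type caudal fin RNA, labelled with Cy3, so that a positive log2 ratio means a higher signal in the transgenic tissue. There were 3 arrays for V600EBRAF, 3 for V12RAS RGP and 3 for V12RAS VGP. A V600EBRAF, RGP or wild-type pool held 10 fins, and a VGP pool held 6 tumours. The files pair the probes with no gene names, so each probe is identified by its ID and its sequence, and groups of probes by peptide motifs encoded in those sequences.

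After averaging of repeated sequences, 42152 distinct probe sequences were available and 32039 passed the detection filter. The share of spots well above background ranged from 70.6% to 76.2% in the Cy3 channel and from 64.0% to 74.8% in the Cy5 channel. The number of arrays, 3 per group, limits the precision of every value. Across probes, the log2 ratios correlated within groups with r between 0.71 and 0.84 for V600EBRAF, between 0.73 and 0.83 for RGP and between 0.85 and 0.94 for VGP. The correlation between arrays of different groups reached 0.67, for the third V600EBRAF and the third RGP array, which lay on the same slide. Probes are not independent replicates, and these correlations only describe the arrays.

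**Figure D1:**
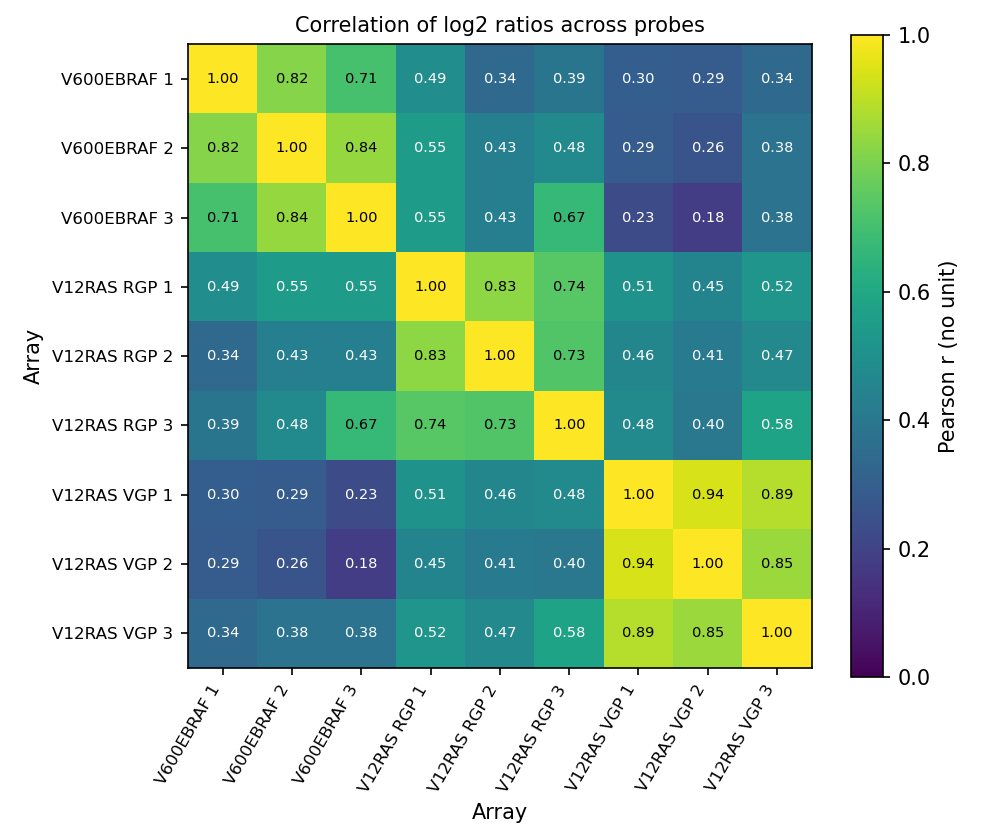
Pearson correlation (no unit) of the normalized log2 ratios across probes for every pair of the 9 arrays, named by group and replicate. The 3 VGP arrays form the tightest block, with r from 0.85 to 0.94.

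The first comparison asked how fins of V600EBRAF fish differed from wild-type fins. The probe LOLS00194 (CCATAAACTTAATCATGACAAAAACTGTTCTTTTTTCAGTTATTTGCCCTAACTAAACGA) had the largest decrease, a log2 ratio of -6.53 ± 0.68 (limma SE, n = 3 arrays, adjusted p = 0.00026), negative on 3 of 3 arrays. The probe A_15_P102324 followed at -5.76 ± 0.52. The largest increases were smaller, 3.43 ± 0.41 for A_15_P102888 and 3.30 ± 0.60 for LOLS03767. Scaling between arrays gave -9.03, -8.27, 4.93 and 4.34 for these 4 probes, median centring -5.37 for A_15_P102324, and LOLS00194 was at -7.19 without V600EBRAF replicate 1. The decreases of LOLS00194 and A_15_P102324 were also large in VGP tumours, where the mean log2 ratios were -6.82 ± 0.48 and -5.93 ± 0.04 (SD, n = 3), and in RGP fins these ratios were -2.98 ± 2.22 and -2.95 ± 1.86. The rising probes A_15_P102888 and LOLS03767 were also positive in VGP tumours, at 3.01 ± 0.54 and 2.94 ± 1.55. In RGP fins they were at 2.18 ± 1.4 and 0.4 ± 1.27. A probe's dye bias stays in all these ratios. All 4 probes that encode a peptide typical of actin, the main protein of the thin filaments of the cytoskeleton and of muscle, rose in V600EBRAF fins, with log2 ratios from 1.23 to 1.37. These were among the brightest probes of the array, and 418 other probes of similar brightness had a median log2 ratio of 0.58. LOLS00001 among the actin-type probes is the sequence on 172 spots, which entered the loess fit. Whether the 4 read separate transcripts is not known. With median centring the actin-type ratios were 2.52 to 2.69 beside a median of 1.85 for the other bright probes, and with the scanner software's ratio 0.72 to 0.85 beside 0.15.

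Of the 32039 probes tested, 4285 were higher and 6728 lower in V600EBRAF fins at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 11013 in all. A change of at least 2-fold was found for 473 higher and 2499 lower probes. The balance of directions depended on the normalization: with median centring in place of loess, 5426 probes were higher and 2892 lower (2077 and 1437 at least 2-fold), and with the scanner software's own ratio 6890 were higher and 6761 lower. The count was 3799 without replicate 2, 4897 without replicate 3 and 8532 on the first scan day alone.

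V12RAS RGP fins were then compared with wild-type fins, where the RAS transgene cannot be told apart from the tissue labelled RGP. The signal of A_15_P109009 (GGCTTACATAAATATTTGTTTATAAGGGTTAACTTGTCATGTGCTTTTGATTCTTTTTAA) was lower in RGP fins, with a log2 ratio of -8.26 ± 0.30 (limma SE, n = 3, adjusted p = 1.6e-06), and that of A_15_P100981 (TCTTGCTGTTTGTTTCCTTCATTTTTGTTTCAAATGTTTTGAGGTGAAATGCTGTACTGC) was at -8.02 ± 0.23. Both probes are bright in wild-type fin, with mean normalized log2 Cy3 signals of 17.19 and 17.89 on these arrays. In V600EBRAF fins the same probes had mean ratios of only -1.68 ± 0.45 and -1.01 ± 0.43 (SD, n = 3). The largest increases, 4.52 ± 0.68 for LOLS00420 and 4.16 ± 0.63 for A_15_P108040, came from 2 probes whose sequences overlap. With median centring these increases were 5.28 and 4.91. The wild-type signal of LOLS00420 was lower on the RGP arrays than on the other arrays, which enlarges its ratio. RGP exceeded V600EBRAF by 4.17 in the ratio and by 2.03 in the Cy5 signals alone. The VGP minus RGP difference was -7.91 in the ratio and -4.94 in the Cy5 signals alone. The 4 actin-type probes rose here as well, by 1.29 to 1.43 on the log2 scale, beside a median of 0.35 for the 418 other bright probes. With median centring they were at 2.51 to 2.62 beside 1.51, and with the scanner software's ratio at 0.93 to 1.12 beside 0.05. Of 6 probes encoding the recognition helix of homeodomain transcription factors, 2 were lower, at -1.36 ± 0.21 and -0.92 ± 0.19, 1 was higher at 0.65 ± 0.10, and 3 did not pass the test. The probe at -0.92 was well above background on 0 of 3 RGP Cy5 channels, so the size of its decrease is uncertain. Of 5 probes encoding a carboxy-terminal signal for retention in the endoplasmic reticulum, 2 were lower, at -2.29 ± 0.28 and -0.55 ± 0.18.

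In RGP fins 5374 probes were higher and 6052 lower than in wild-type fins, of which 1334 and 1606 changed at least 2-fold. Median centring in place of loess left 6704 calls, 4046 of them higher and 2658 lower. The count was 6325 without replicate 2, 5697 without replicate 3 and 8989 on the first scan day alone.

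Under the reported processing VGP tumours showed the widest change from wild-type fin among the 3 groups. The order by calls turned after scaling between arrays, with 15981 probes called for V600EBRAF and 14014 for VGP. Values below are without this scaling unless stated. The probe A_15_P110475 (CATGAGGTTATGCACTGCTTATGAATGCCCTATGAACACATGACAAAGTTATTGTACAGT) was higher by 8.76 ± 0.23 on the log2 scale (limma SE, n = 3, adjusted p = 1.8e-08), and A_15_P120840 by 7.41 ± 0.32. Ratios of these probes were also positive in RGP fins, at 3.91 ± 0.68 and 3.63 ± 0.91 (SD, n = 3), and in V600EBRAF fins, at 1.42 ± 0.27 and 0.99 ± 0.68. The wild-type signal of A_15_P110475 was lower on the VGP than on the V600EBRAF arrays, which enlarges its VGP ratio. Its difference between these groups was 7.35 in the ratio and 3.57 in the Cy5 signals alone. A_15_P113471, whose sequence overlaps that of A_15_P120840, was at 5.87 in VGP tumours and 2.23 in RGP fins. The largest decreases were those of A_15_P100981, -8.76 ± 0.23, and A_15_P109009, -8.41 ± 0.30, the probes that led the decreases in RGP fins. Scaling between arrays brought the changes of A_15_P110475, A_15_P120840, A_15_P100981 and A_15_P109009 to 6.38, 5.40, -6.37 and -6.08. Of 6 probes encoding the glycine-X-Y repeat of the collagen triple helix, the one with the highest signal rose by 2.03 ± 0.20, 1 was lower at -0.59 ± 0.21, and 4 did not pass the test. The homeodomain probe that was lowest in RGP fins was at -2.88 ± 0.21 in VGP tumours (-2.08 after scaling between arrays), 1 other was at -1.01 ± 0.19 but well above background on 0 of 3 VGP Cy5 channels, and 4 did not pass the test. The endoplasmic reticulum retention probe that was lowest in RGP fins was at -3.31 ± 0.28 (-2.42 after scaling). Of the other retention probes 1 was lower, at -1.34 ± 0.18, 1 was higher, at 1.29 ± 0.25, and 2 did not pass the test. Of 3 probes encoding the switch II motif of small GTPases, 1 rose by 2.12 ± 0.16 and 1 was lower at -1.31 ± 0.14. The rising one was well above background on 7 of 9 Cy3 channels, and it was at 3.05 with the scanner software's ratio and at 1.54 after scaling between arrays. Of 3 probes with the catalytic loop of protein kinases, 2 were lower, at -1.89 ± 0.22 and -1.0 ± 0.19. The actin-type probes had ratios of 0.48 to 0.78, against a median of 0.11 for the other bright probes. With median centring they were at 1.78 to 2.03 beside 1.34 and passed the test. With the scanner software's ratio they were at 0.24 to 0.57 beside -0.07 and 3 of the 4 did not pass, nor did any of the 4 after scaling between arrays. For 2 of the 4 the call was also lost without VGP replicate 1 (0.43 and 0.51) or 3 (0.40 and 0.30).

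In VGP tumours 8483 probes were higher and 10001 lower than in wild-type fin, 18484 in all, or 57.7% of those tested. At least 2-fold changes were found for 4007 higher and 5355 lower probes, and at least 8-fold changes for 601 and 799. On the first scan day alone 17874 probes were called. The VGP channel holds tumour tissue and the wild-type channel whole fins, and the cell make-up of neither was measured.

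**Figure D2:**
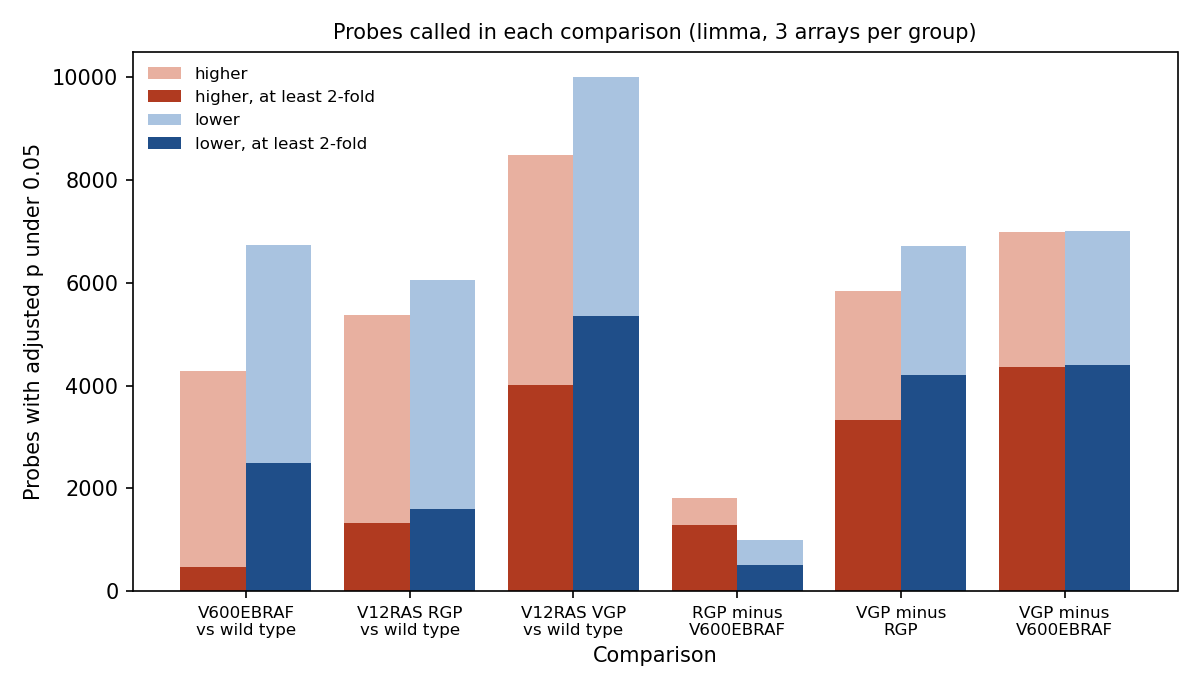
Number of probes with an adjusted p under 0.05 (vertical axis) in each of the 6 comparisons, split into higher and lower signals; the dark part of a bar is the number that changed at least 2-fold. VGP tumours against wild-type fin gave 8483 higher and 10001 lower probes, and RGP against V600EBRAF fins 1820 and 988.

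RGP fins were compared directly with V600EBRAF fins, with the probe-specific dye bias cancelling. Only V12RAS samples carry the label RGP, so the oncogene cannot be told apart from the kind of tissue. The cell make-up of these fins was not measured. The signal of A_15_P100981 was lower in RGP fins, with a log2 difference of -7.01 ± 0.32 (limma SE, n = 3 per group, adjusted p = 4.4e-05; -7.97 with median centring), as was that of A_15_P109009, at -6.58 ± 0.43 (-7.47 with median centring). A_15_P107673 was higher in RGP fins by 5.01 ± 0.69, with ratios to wild-type of 1.39 ± 0.75 in RGP and -3.62 ± 1.56 in V600EBRAF fins (SD, n = 3). The difference was 6.51 after scaling between arrays, 4.13 without V600EBRAF replicate 2 and 5.63 without V600EBRAF replicate 3. LOLS00420 was higher by 4.17 ± 0.96, with an adjusted p of 0.029 that ranged up to 0.11 over the alternatives. Its 3 V600EBRAF ratios ran from -2.09 to 3.04. This call was lost without V600EBRAF replicate 2 (4.05), without RGP replicate 1 (4.18), 2 (4.08) or 3 (4.24), with the Cy5 signals alone (2.03) and after scaling between arrays (5.6). The difference itself was 2.95 without V600EBRAF replicate 1 and 5.51 without V600EBRAF replicate 3. The homeodomain probe that was lowest in RGP fins was also lower there than in V600EBRAF fins, at -1.62 ± 0.30, a call lost without RGP replicate 2, where the value was -1.40. Another homeodomain probe was higher, at 0.53 ± 0.14, and 4 did not pass the test. The endoplasmic reticulum retention probe was lower, at -2.87 ± 0.39, and the 4 other retention probes did not pass the test, while the 4 actin-type probes differed by -0.07 to 0.20 and did not pass the test.

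Between RGP and V600EBRAF fins 1820 probes were higher and 988 lower in RGP, 2808 in all. The count rose to 4237 with the replicate number as a block, to 5946 with slide as a fixed block and to 4943 with scan day as a block, and was 2407 within slide 1, which held 2 arrays of each group. It fell to 821 without V600EBRAF replicate 2, 1445 without V600EBRAF replicate 3, 850 without RGP replicate 2 and 1486 without RGP replicate 3. Median centring gave 642 higher and 561 lower probes.

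The comparison of VGP tumours with RGP fins contrasted the 2 kinds of V12RAS tissue. LOLS00420, the probe with the largest rise in RGP fins, was lower in VGP tumours, with a log2 difference of -7.91 ± 0.96 (limma SE, n = 3 per group, adjusted p = 0.00019), its ratio to wild-type changing from 4.52 ± 0.16 to -3.40 ± 0.13 (SD, n = 3). Its difference was -4.94 with the Cy5 signals alone and -9.32 with slide as a fixed block. LOLS10981 was lower as well, at -7.51 ± 0.32 (-5.97 after scaling between arrays and -8.21 with median centring), with ratios of 1.3 ± 0.53 in RGP and -6.21 ± 0.50 in VGP. Higher signals in VGP tumours were led by A_15_P116602, at 7.42 ± 0.92, and LOLS00581, at 7.08 ± 1.04. The VGP ratios of these 2 probes varied widely, from 3.73 to 8.42 and from 2.32 to 7.63. Their differences were 6.04 and 5.70 without VGP replicate 2, 8.39 and 8.36 without VGP replicate 3, and 5.51 and 4.55 with slide as a fixed block. The small GTPase probe that rose in VGP tumours was higher than in RGP fins by 1.89 ± 0.23, by 2.83 with the scanner software's ratio and by 1.25 after scaling between arrays; it was well above background on 2 of 3 RGP Cy5 channels. Another small GTPase probe was lower in VGP tumours, at -0.66 ± 0.19. In all, 5842 probes were higher and 6717 lower in VGP tumours than in RGP fins, and 3339 and 4210 of them differed at least 2-fold; with median centring 3257 were higher and 5259 lower. VGP replicates 1 and 2 lay on a slide of their own. With slide as a fixed block 10440 probes were called, with scan day as a block 15093, with the replicate block 14599, and after scaling between arrays 8055.

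Against V600EBRAF fins, VGP tumours had higher signals of A_15_P110475, by 7.35 ± 0.33 (adjusted p = 1e-06), and of LOLS01611 (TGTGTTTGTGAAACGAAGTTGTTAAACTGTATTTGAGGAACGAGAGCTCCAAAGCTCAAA), by 7.29 ± 0.37 (limma SE, n = 3 per group). LOLS01611 had a ratio to wild-type of -0.08 ± 0.09 in V600EBRAF fins, 3.33 ± 0.90 in RGP fins and 7.21 ± 0.14 in VGP tumours (SD, n = 3). The largest decreases were again those of A_15_P100981, -7.75 ± 0.32, and A_15_P109009, -6.72 ± 0.43. When the Cy5 signals alone were compared, the difference of A_15_P110475 was 3.57, since its wild-type signal was also lower on the VGP arrays. Scaling between arrays gave 4.37 for A_15_P110475, 5.41 for LOLS01611, -4.73 for A_15_P100981 and -3.52 for A_15_P109009, and median centring -8.84 and -7.70 for the last 2. The collagen-type probe that rose in VGP tumours was higher than in V600EBRAF fins by 2.45 ± 0.29, while another collagen-type probe was lower, at -1.35 ± 0.30, and 4 did not pass the test. The homeodomain probe was lower at -3.13 ± 0.30 (-2.44 after scaling between arrays), while another homeodomain probe was higher, at 1.12 ± 0.36, and 4 did not pass the test. In all, 6989 probes were higher and 7003 lower, 13992 together, and with median centring 3909 were higher and 6625 lower. With slide as a fixed block 11636 probes were called, and with scan day as a block 16560.

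**Figure D3:**
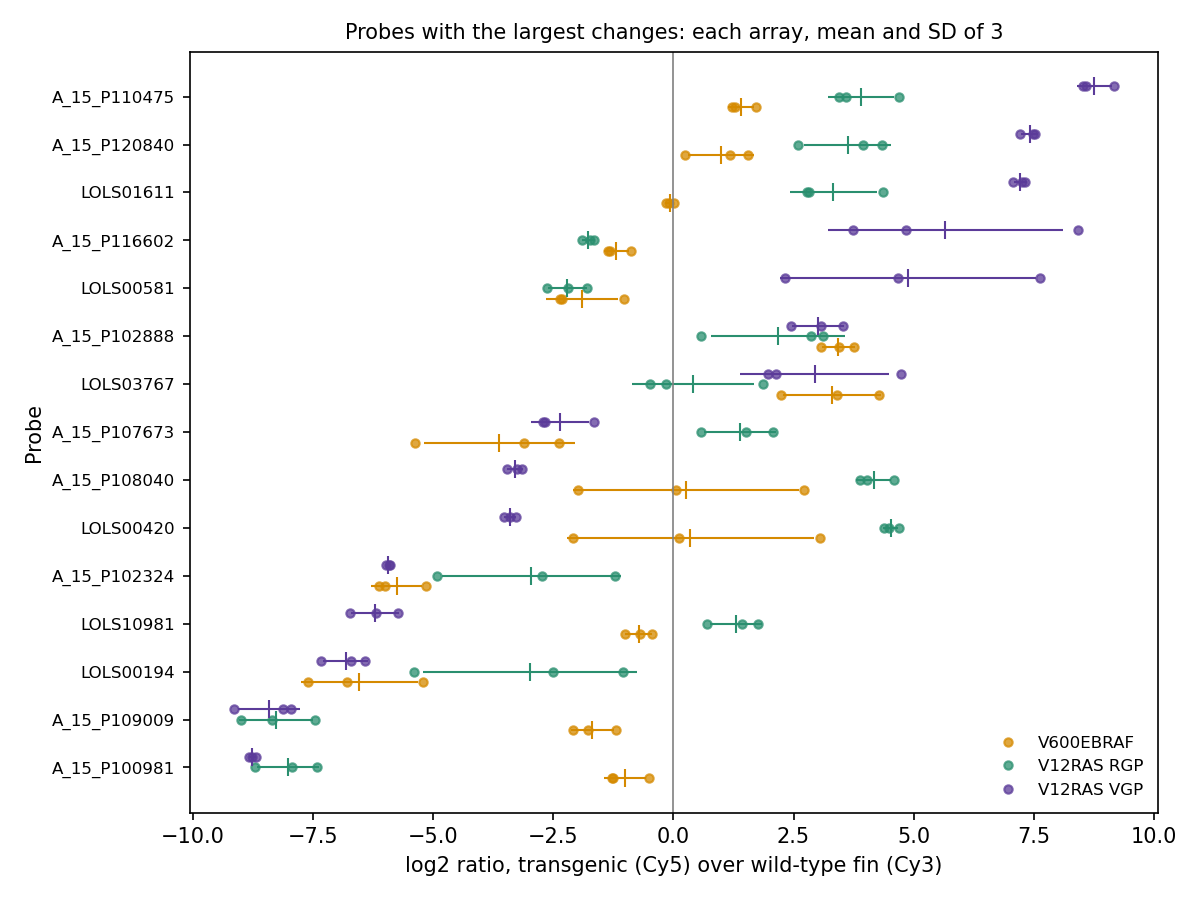
Log2 ratio of transgenic (Cy5) to wild-type (Cy3) signal on each array (horizontal axis) for the probes with the largest changes (vertical axis); dots are single arrays, ticks the mean of 3 arrays and bars the SD. A_15_P100981 lies near -1 in V600EBRAF fins (mean -1.01) and at -8.02 and -8.76 in RGP fins and VGP tumours.

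The mean ratios of the groups were compared with each other across the 32039 probes. The correlation was 0.58 between V600EBRAF and RGP, 0.54 between RGP and VGP, and 0.33 between V600EBRAF and VGP (Pearson's r; Spearman's rho 0.58, 0.49 and 0.32). The covariances were 0.226, 0.433 and 0.259. Simulated unchanged groups that shared a wild-type pool per replicate number gave a covariance of 0.024 in each case, and a correlation of 0.50, 0.49 and 0.49. Between arrays of different scan days the covariances were 0.228, 0.448 and 0.258, and between arrays of the same day 0.224, 0.423 and 0.260. The labels do not say which wild-type pool was used on which array, and a constant dye bias of a probe adds to each covariance. V600EBRAF and RGP fins had 2014 higher and 3322 lower probes in common, where independent lists would share 718.7 and 1271. RGP and VGP had 2947 higher and 3851 lower probes in common, against 1423 and 1889, and V600EBRAF and VGP had 1768 and 3541, against 1135 and 2100. Independence is not the value for unchanged groups, because the lists share the dye orientation and possibly the wild-type pools. No expectation with shared pools was calculated for these lists. In all 3 groups 1114 probes were higher and 2214 lower than in wild-type fin.

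Other orders of change across the groups were counted from the tests of the differences themselves. In VGP tumours 2085 probes were above wild-type fin and above both other groups while neither of these passed the test against wild-type, and 2095 probes were below all of them in the same way. Of the probes higher in RGP fins than in wild-type fins, 1297 were higher again in VGP tumours than in RGP fins, and 1516 were lower in VGP tumours than in RGP fins; independent lists would give 979.9 and 1127. Of the probes lower in RGP fins than in wild-type fins, 1417 were lower again in VGP tumours than in RGP fins and 1154 were higher; independent lists would give 1269 and 1104. These pairs of lists share the RGP arrays. V600EBRAF fins stood above wild-type fins and above both RAS groups for 377 probes, and below all of them for 544.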

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

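All tests weighed here except the counts of other splits and sign patterns were chosen after the result was seen. Groups of 3 arrays are too small for a search for outlying arrays.

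Between RGP fins and VGP tumours, 1059 probes were called against wild-type in opposite directions with the difference itself called, 673 higher and 386 lower in RGP. Between V600EBRAF fins and VGP tumours there were 1785 such probes, 978 higher and 807 lower in V600EBRAF, and between V600EBRAF and RGP fins 381, 163 higher and 218 lower in V600EBRAF. Opposite calls were fewer than independent lists would give, which is 1677 and 1602 for RGP and VGP. For V600EBRAF and VGP independent lists would give 1338 and 1781, and for V600EBRAF and RGP 809.4 and 1129. Among the named probes, LOLS00420 and A_15_P108040, which overlap, rose in RGP fins and were below wild-type in VGP tumours, with differences of -7.91 and -7.45 on the log2 scale (-4.94 and -5.29 with the Cy5 signals alone, -9.32 and -8.71 with slide as a fixed block). LOLS10981 was above wild-type in RGP fins and below it in both other groups; RGP exceeded V600EBRAF by 2.02 (1.46 with the Cy5 signals alone), and VGP minus RGP was -7.51. LOLS00581 was below wild-type in RGP fins and above it in VGP tumours, a difference of 7.08 (4.55 with slide as a fixed block).

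The replicate 3 arrays of all groups deviated together, and blocks for slide, day or number raised the count of calls between RGP and V600EBRAF from 2808 to at least 4237. The difference of the second-day array and the mean of the first-day arrays was taken within each group from the normalized Cy3 signals. It correlated between groups by 0.65 (V600EBRAF and RGP), 0.47 (V600EBRAF and VGP) and 0.55 (RGP and VGP). An effect of scan day or slide would give such correlations. This channel was labelled from wild-type RNA, but its normalized signals are not fully free of the Cy5 channel, so the values do not settle the cause. If each replicate number stood for a shared wild-type pool and the pools differed enough, the difference of replicates 1 and 2 would correlate between groups on the first day. The lowest of the 3 correlations was -0.11 and the highest 0.07. These values show no pool effect shared by those numbers. Pools that differ little would also give low correlations, and their spread was not measured, so shared pools themselves stay open. Slide 2 was the only slide of the second day, so day and slide cannot be separated, a wild-type pool used only on slide 2 stays open, and no biological explanation was tested.

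Wild-type signals of bright probes fell where the transgenic signal was higher. On slide 2, among the 500 brightest probes, the slope of the wild-type difference between arrays on the transgenic difference was -0.44 for RGP minus V600EBRAF, -0.724 for VGP minus RGP and -0.682 for VGP minus V600EBRAF in signals that were only background subtracted. These values argue against normalization between arrays as the cause, and the gap to the slope of middle-range probes was -0.456 or lower in each pair, which argues against different wild-type pools acting alike on all probes. Competition of the labelled RNAs for bright probes stays open: the slope nearest to 0, -0.44, is the pattern itself and does not test it. Whether the ratio or the Cy5 signal alone is nearer to the true change of such probes stays open, and no biological explanation was tested.

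Ratios of the 3 groups went together across probes. A dye bias common to all arrays would give equal covariances, and the largest and smallest differed by 0.207, so that it cannot be the whole cause, though up to the smallest covariance may still come from it. Covariances between arrays of different scan days were at least 0.992 times those within days, which argues against a shared day as the whole cause. The observed covariances were at least 9.42 times those simulated for shared wild-type pools. That simulation gave each replicate number its own pool and drew the pool effect from the spread within groups. It argues only against pools shared in that way. A pool or wild-type difference common to all arrays of a group lies outside that spread and was not weighed. Changes common to transgenic fins and tumours stay open as a hypothesis. They were not separated from a dye bias or from a wild-type difference common to the arrays.

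With 3 arrays against 3 there are 10 splits, and with 3 arrays against wild-type 4 sign patterns, too few for a share under 0.05. In each of the 6 comparisons 1 split or pattern, the real one, gave as many calls. For RGP against V600EBRAF the real split gave 2808 calls and the highest other split 1; for VGP against RGP 12559 and 0; for VGP against V600EBRAF 13992 and 0. Turning the sign of an array left at most 0 calls in each group, beside 11013, 11426 and 18484 with the real signs. Every other split mixes arrays of both groups, and a turned sign sets 1 array against the others. A real difference then enters the spread, so few calls follow by construction and these counts do not weigh chance.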

How the results depend on the processing

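The scan day block, the first scan day alone and 1 probe per overlap cluster were added after the data were seen, as were the alternatives for peptide classes. Of the counts of calls under alternatives, 144 stayed within 1.5 times the reported count and 22 did not. A 2-fold minimum left 2972 calls for V600EBRAF, 2940 for RGP and 9362 for VGP against wild-type, and 1795, 7549 and 8762 for RGP minus V600EBRAF, VGP minus RGP and VGP minus V600EBRAF, as its construction implies. Median centring without loess gave 6704 calls for RGP against wild-type and 1203 for RGP minus V600EBRAF; it moved the median of all probes to 0.179 in V600EBRAF and to -0.17 in VGP minus V600EBRAF (from -0.025 and 0.009). Scaling between arrays gave 4775 calls for RGP minus V600EBRAF and 8055 for VGP minus RGP. Against wild-type it gave 15981 for V600EBRAF and 14014 for VGP, which turned their order by calls. Scaling gives every array the same median absolute ratio, so it widens narrow groups and narrows wide ones by construction. The cause of the changes with median centring was not tested. RGP minus V600EBRAF also rose to 5946 with slide as a fixed block, 5492 with slide as a random block, 4943 with scan day and 4237 with the replicate block. The replicate block moved no other count by over 1.5 times, and for the other comparisons it gave 13572, 14063, 20211, 14599 and 16015 calls. Slide as a random block lowered the counts against wild-type, to 8304 for V600EBRAF, 9205 for RGP and 17069 for VGP. Its estimated correlation of arrays within a slide was 0.371, while the reported tests treat these arrays as independent.

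Leaving out 1 array gave 3799 to 12791 calls for V600EBRAF, 5697 to 13307 for RGP, 15722 to 18665 for VGP, 821 to 4049 for RGP minus V600EBRAF, 9964 to 12895 for VGP minus RGP and 11199 to 14418 for VGP minus V600EBRAF. The correlations between groups stayed at 0.52 to 0.61, 0.49 to 0.57 and 0.28 to 0.36.

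Among 1816 values of single probes under alternatives, 1680 kept direction and call, 135 kept the direction only, and 1 turned: a probe with a serine protease motif, which also occurred on the reverse strand of 1 probe, in VGP minus V600EBRAF, -0.97, was 0.93 after scaling between arrays. The call of the retention signal class between RGP and V600EBRAF passed under the replicate block, adjusted p 0.039 (0.07 without; 0.23 with the block and an estimated correlation, 0.22 with the estimated correlation alone). Alternatives were run for the probes named by ID, in the comparisons they were listed or flagged for, the 4 actin-type probes and 1 further probe of each of 6 peptide classes, not for the other class members. Not run, for want of gene names, were 1 probe per named gene and all alternatives of the gene list shifts; the value table equals the scanner's ratios, and slide 2 alone has 1 array per group and no test. Low signal over background limits dim probes: 24753 probes were well above background in both channels of all arrays.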

Other observations

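The peptide classes described here, the overlap of probes and the split by scan day were chosen for the text after their values were seen. Detection calls gave a view of probes near the background. In VGP tumours 179 probes were well above background on all 3 Cy5 channels and on none of the 9 wild-type channels, against 30 in RGP fins and 25 in V600EBRAF fins. Of the 30 RGP probes, 24 were also among the 179 of VGP, and 118 of the 179 were not well above background on any Cy5 channel of the other groups. In the other direction, 690 probes were well above background in wild-type fin on all 9 arrays and on no VGP Cy5 channel, beside 592 for RGP and 494 for V600EBRAF. For 205 of the 690, all 6 V600EBRAF and RGP Cy5 channels were well above background. The Cy5 and Cy3 detection limits differ, and no test was run on these counts.

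Of the 6 probes with the immunoglobulin fold cysteine motif, a feature of antibodies and many surface receptors, 4 were lower in VGP tumours. Those at -1.30, -1.06, -0.83 and -0.62 passed the test in limma. None of these 4 was well above background on any VGP Cy5 channel, so that the sizes are uncertain. The class as a set did not pass (camera, adjusted p = 0.35, and 0.78 with an estimated correlation). Of 2 probes with an epidermal growth factor-like motif, both had ratios below wild-type in VGP tumours, -1.52 and -0.76, and the second was above it in V600EBRAF and RGP fins, at 0.90 and 0.81.

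Different probes with overlapping sequence served as a technical check. Among 2879 pairs of tested probes that share at least 20 bases, the log2 ratios correlated by 0.98 for VGP, 0.94 for RGP and 0.83 for V600EBRAF against wild-type. Where both probes of a pair were called in VGP tumours, 1670 of 1677 pairs had the same direction, as had 862 of 874 pairs in V600EBRAF fins. At least 1 probe was called in 1987 pairs in VGP tumours and in 1452 pairs in V600EBRAF fins, so in the remainder only 1 probe of the pair passed. Calls from the first scan day alone, with 2 arrays per group, had the same sign on the single second-day arrays for 96.8% of the 2131 probes called between RGP and V600EBRAF, and for 94.9% of the 12331 called between VGP and RGP.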
